A study of Drosophila melanogaster with 6 samples.

How the data were processed

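RNA was measured by sequencing in 6 libraries of S2 cells, a hemocyte-like line derived from Drosophila melanogaster embryos. The labels put 3 libraries in a control group that received medium alone and 3 in a group exposed to 10 mM H2O2 (hydrogen peroxide) for 30 min at 25 °C. Cells were kept in medium with 10% serum. Per the labels' protocols, RNA was isolated with Trizol and a column kit, and libraries were made with a stranded poly(A) mRNA kit. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

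The deposited files hold 1 row per gene. Per the submitters' processing notes, the tools were STAR 2.4.0j and RSEM 1.2.21, with genome build dm6; the annotation release is not given in the sources used here. Per the file headers, the authors' RSEM tables give an expected count (reads shared between genes are divided by probability), a TPM value (a share of transcripts, scaled by effective length), and gene and effective lengths with a posterior SD of the count. The expected counts were the main measurement. The deposited TPM values were used only in alternatives, because they keep no depth. Where a near-identical copy shares reads, the split is uncertain, and the posterior SD was read for that.

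The files list 16451 genes, of which 16419 matched a symbol and a position. Symbols and coordinates came from the Ensembl release 115 annotation (BDGP6.54, the assembly also called dm6). Library totals were 36947768, 39253171 and 36806499 expected counts in control replicates 1, 2 and 3, and 35404927, 42043808 and 38059138 in H2O2 replicates 1, 2 and 3. Mitochondrially encoded genes are not among the genes analysed here.

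Expected counts were rounded to whole numbers. edgeR 4.0.16 (R 4.3.3) kept 8955 genes by filterByExpr, holding 99.975% of the counts, and scaled libraries by TMM. A quasi-likelihood F test (robust, two-sided, group as the only term) compared H2O2 with control, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A positive log2 fold change means higher after H2O2. Its standard error (SE) is the fold change divided by the square root of F. CPM below means TMM-normalized counts relative to the library total, given as mean ± SD with n = 3 per group.

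Both groups carry replicate numbers 1 to 3. Deviations from the group means correlated across genes at 0.717, 0.518 and 0.601 for the same-numbered libraries 1, 2 and 3. The numbers were therefore read as pairing the libraries. That pairing comes from the data, since the labels give only the shared numbers. A second fit with the replicate number as a block is given beside a result where it changes a call, for gene lists as the count of called members. No libraries were duplicates: a chi-square comparison of counts gave between 49.3 and 231 per degree of freedom over the 15 library pairs.

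Before the data were examined, 26 gene lists were fixed: immediate-early and stress transcription factors, JNK, p38, heat shock and chaperone, antioxidant, unfolded protein and integrated stress response, NF-kB, JAK/STAT, p53 and DNA damage, metal response, ecdysone, Notch targets, Ras-ERK, cell cycle, glycolysis and pentose phosphate pathway, ribosomal proteins, proteasome, nuclear and mitochondrial oxidative phosphorylation, histones, autophagy, and markers of hemocytes, ovary, neurons, muscle, and fat body with epithelium. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided, adjusted over 25 lists. Camera with an estimated correlation was run beside it, and fry, which asks a different question: whether a list differs from no change, not from the other genes.

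The rule for named genes was fixed at the same time. It took the 10 highest and 10 lowest fold changes among called genes with a mean of at least 5 CPM and no overlap between groups. It added, from each list, the 4 called members with the smallest p or, where none was called, the 2 most abundant members. The genes p38a, p38b, lic, Atf-2 and Mef2 were added because the series title names p38. A further gene that the rule takes is not reported here. Other genes named were chosen after their values were seen: esg, RNaseMRP:RNA, RNaseP:RNA, E(spl)mdelta-HLH, N, asRNA:CR44370, lncRNA:CR45204, Hsp70Ab, Hsp70Bb, Hsp68, Hsp83, Hml, GstD1, se, Thor, upd2, rpr, Atf3, CG2269, CG13992 and Vha100-4, with their neighbours.

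The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 changed genes. The simulation for the blocked fit added a random replicate effect to each gene, and that for the unblocked fit had no pairing of libraries. For H2O2 against control, the unblocked fit tested 8837 simulated genes and recovered 56.6% of the 2-fold and 89.6% of the 4-fold changes, with 12 unchanged genes called. The blocked fit tested 8871 simulated genes and recovered 94.9% and 100% of them, with 22 unchanged genes called. The list test, on 8843 simulated genes, passed the 1 list of 40 genes shifted by 0.8 log2 and 0 of 20 unshifted lists. These genes were drawn independently of each other. In the real data the estimated correlation within a list reached 0.596 for ribosomal protein and 0.733 for oxidative phosphorylation genes. The simulation therefore cannot show how the list test behaves for such lists or for smaller shifts.

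Alternatives were DESeq2 1.42.0, other scaling factors, no filter and a filter of 50 counts in 3 libraries, unrounded counts, an effective length offset, limma on log2(TPM + 1) and log2(TPM + 0.1), removal of a smooth gene length trend, the replicate block, a test against a 1.2-fold change, and leaving out each library. Leaving out both libraries of a number, with and without the block, and the estimated correlation in the alternative fits were added after seeing the data. For list tests with the length trend removed or an effective length offset, the correction was subtracted from log2 CPM that appears to hold it already. Those list tests may be overcorrected, so no conclusion is drawn from their signs and p-values. Fold changes, list medians and calls of single genes are not affected.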

Results

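The transcriptome of S2 cells was measured in 3 control libraries and 3 libraries from cells exposed to 10 mM H2O2 for 30 min. The series title places the comparison in a study of nuclear p38, a stress-activated kinase, in the transcriptional response to oxidative stress. Genes with a count above 0 numbered 11181, 11322 and 11218 in control replicates 1 to 3, and 11612, 12080 and 11819 in H2O2 replicates 1 to 3. The first principal component held 48.4% of the variance and separated the groups. The second held 30.5% and separated replicate 1 from replicates 2 and 3 in both groups.

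After H2O2, mostly low-abundance genes were higher and mostly long, abundant transcripts were lower. The snail-family transcription factor gene esg (FBgn0287768, chromosome 2L, 15333866 to 15336138) went from 0.277 ± 0.0979 to 8.68 ± 4.20 CPM (n = 3 per group), and several genes of the Enhancer of split complex, known as Notch targets, were higher. The cytoskeletal linker gene shot (FBgn0013733, chromosome 2R, 13864237 to 13942110) fell from 841 ± 83.1 to 429 ± 15.1 CPM, and the dynein heavy chain gene Dhc64C from 709 ± 75.2 to 395 ± 62.4 CPM. The size of both decreases depended on the processing. Over all fits, the log2 fold change ranged from −1.07 to −0.28 for shot and from −0.98 to −0.21 for Dhc64C. Genes of the p38 pathway itself were not called without the replicate block.

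In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 281 of 8955 genes were called, 230 higher and 51 lower. Of these, 228 higher and 7 lower genes had an absolute log2 fold change of at least 1. With the replicate block, 1947 genes were called, 805 higher and 1142 lower, including all 230 and all 51. The higher share of calls was 81.9% without the block and 41.3% with it, and 51.0% by DESeq2. The calls without the block depended on single libraries: 0 genes were called by edgeR without control replicate 2, control replicate 3 or H2O2 replicate 2, where 1054, 1054 and 891 genes had an unadjusted p under 0.05. The smallest adjusted p in these fits was 0.0669, 0.0744 and 0.0558. In these fits the median log2 fold change was 2.79, 2.62 and 2.50 for the 230 genes and −0.69, −0.70 and −0.66 for the 51, with 0 signs turned. Over all 6 libraries the medians were 2.68 and −0.72. The genes were chosen by their difference in all 6 libraries, and each of these fits reuses most of those libraries. Their medians and signs were therefore likely to stay, which gives no independent support. Without control replicate 1, H2O2 replicate 1 or H2O2 replicate 3, 91, 154 and 113 genes were called. Groups did not overlap in 894 genes higher and 934 genes lower after H2O2, 20.4% of genes tested, where chance gives 10% for 6 exchangeable libraries, a value that ignores the pairing.

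Among called genes with a mean of at least 5 CPM, the largest increases were in yellow-c, CG7509, Galphaf, FASN2, CG8907 and CG5707. The gene yellow-c (FBgn0041713, chromosome 2L, 15035394 to 15037841) went from 1.30 ± 0.571 to 9.16 ± 4.69 CPM, a log2 fold change of 2.82 (SE 0.46, adjusted p = 0.0282). CG7509 had a log2 fold change of 2.52 and Galphaf, a G protein alpha subunit gene, of 2.21. FASN2, a fatty acid synthase gene, had 2.16, CG8907 2.12 and CG5707 2.05. The protease gene rho, which acts in Egfr ligand processing, rose from 15.5 ± 3.34 to 54.6 ± 26.4 CPM (log2 fold change 1.82, adjusted p = 0.0406), and CG43338 had 1.81. CG7509 lies on chromosome 3L at 4803077 to 4805274, 2.09 kb downstream of Dhc64C on the same strand. CG8907 lies 1.06 kb downstream of Irc and Galphaf 3.73 kb downstream of zetaCOP, also on the same strand.

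The signal recognition particle RNA copies 7SLRNA:CR32864 and 7SLRNA:CR42652 each had a log2 fold change of 1.91 (SE 0.20, adjusted p = 0.0134), but they are near-identical and share their reads, so the split between them is uncertain. RNaseMRP:RNA, on chromosome 3R at 23730048 to 23730429, went from 1.19 ± 0.322 to 8.57 ± 2.05 CPM, and RNaseP:RNA, the other ribonuclease RNA, from 1.94 ± 0.332 to 6.81 ± 1.30 CPM. Their log2 fold changes were 2.85 and 1.81.

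**Figure D1:**
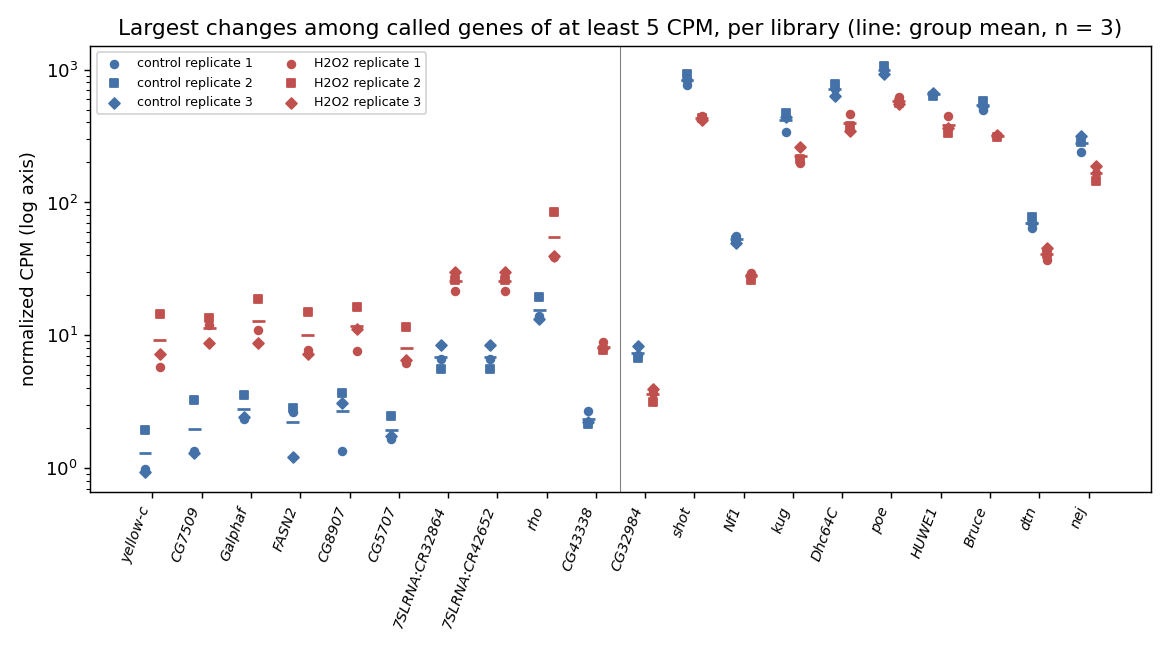
Normalized CPM (log axis) of the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between groups, for each of 3 control and 3 H2O2 libraries, with a line at each group mean. The first 10 genes are higher after H2O2 and the last 10 lower; shot, for example, had means of 841 and 429 CPM.

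Among called genes with a mean of at least 5 CPM, 9 of the 10 largest decreases were in genes with transcripts of at least 8641 nt. Beside shot (log2 fold change −0.97, SE 0.12, adjusted p = 0.0134) and Dhc64C (−0.84), they were the Ras GTPase-activating gene Nf1 (−0.92), the cadherin gene kug (−0.89), the ubiquitin ligase genes poe (−0.79), HUWE1 (−0.78) and Bruce (−0.78), dtn (−0.77) and the CBP acetyltransferase gene nej (−0.77). The largest decrease among the 10, −1.04, was in CG32984, with a transcript of 1960 nt. The 51 lower genes had a median transcript length of 9405 nt, against 1873 nt for all tested genes, and a median log2 fold change of −0.72. Over genes of at least 5 CPM, the median log2 fold change was 0.16 for transcripts up to 1000 nt and −0.57 for transcripts over 8000 nt. With the length trend removed, 10 genes were called lower, and 8 of the 51 were among them. The median log2 fold change of the 51 was then −0.21. Over all fits, the weakest value was −0.28 for shot, −0.43 for Nf1, −0.26 for kug, −0.21 for Dhc64C and −0.32 for dtn. It was −0.12 for poe and Bruce, −0.11 for HUWE1 and nej, and −0.85 for CG32984. The slope of log2 CPM on length also varied between controls, from 0.00369 to 0.119 per doubling of length.

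**Figure D2:**
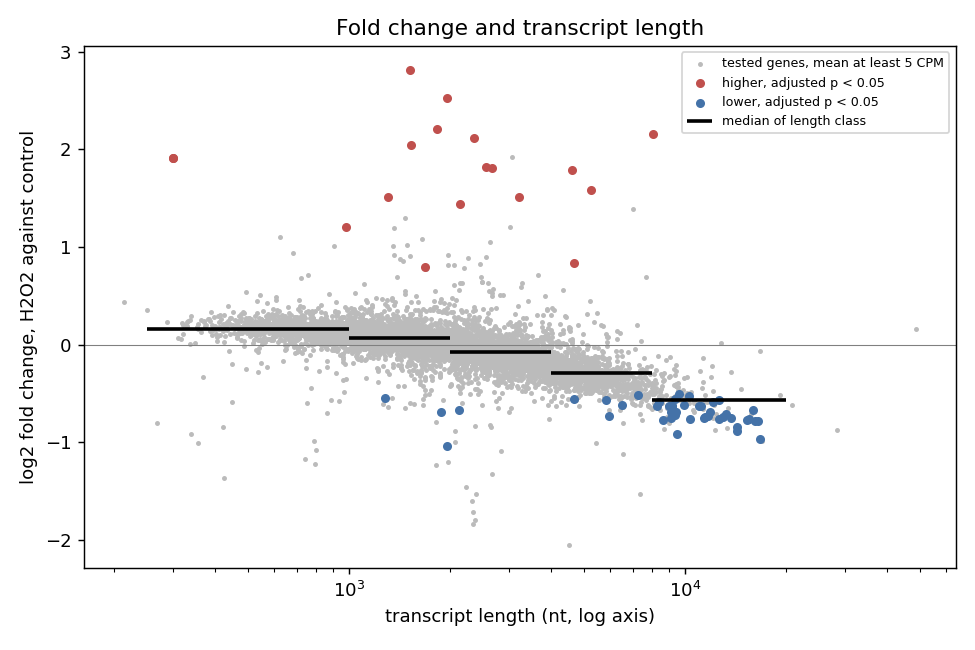
The log2 fold change against transcript length (nt, log axis) of genes with a mean of at least 5 CPM; colours mark genes called higher or lower, and black bars give the median of each length class. The medians go from 0.16 in the shortest to −0.57 in the longest class.

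Most higher genes were of low abundance: 212 of 230 had a mean under 5 CPM. All 230 together had a median of 0.702 CPM and a median log2 fold change of 2.68. Of the 199 called genes with under 1 CPM in controls, 134 lay within 5 kb downstream of an expressed gene (at least 10 CPM) on the same strand. Examples are CG2269 downstream of the TNF gene egr (0.852 ± 0.339 to 7.67 ± 2.55 CPM), CG13992 downstream of the profilin gene chic (0.866 ± 0.395 to 7.83 ± 2.86 CPM), and Vha100-4 downstream of Vha100-2 (0.974 ± 0.439 to 6.81 ± 2.08 CPM). The upstream genes egr, chic and Vha100-2 had log2 fold changes of 0.02, 0.09 and −0.04, none called.

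**Figure D3:**
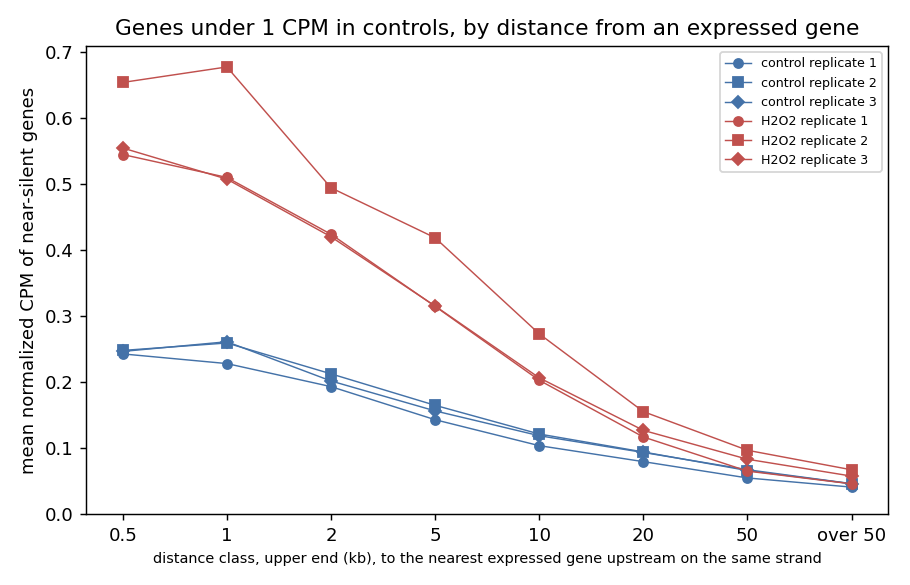
Mean normalized CPM, per library, of genes with under 1 CPM in controls, by distance class (kb) from the nearest expressed gene upstream on the same strand. Within 0.5 kb the group means were 0.246 CPM in controls and 0.584 CPM after H2O2; beyond 50 kb they were 0.0448 and 0.0573 CPM.

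Of the stress-response lists, few members were called. In the p38 list, 0 of 13 tested members were called by edgeR without the block and 4 were lower with it. p38a had 93.2 ± 25.9 CPM in controls and 94.4 ± 21.6 CPM after H2O2 (log2 fold change 0.02, SE 0.24), and p38b 72.7 ± 5.77 and 75.9 ± 8.27 CPM (0.06, SE 0.12). The p38-activating kinase gene lic (−0.01), Atf-2 (0.02), Mef2 (−0.22) and Lk6 (−0.27) had adjusted p between 0.346 and 0.986, and Lk6 was called lower with the block (0.0193), but had 0.02 with the block and the length trend removed (adjusted p = 0.935), where 0 of the 13 p38 genes and 0 of the 18 JNK genes below were called. In the JNK list, 0 of 18 members were called by edgeR without the block and 5 were lower with it, and chic (0.09) and kay (0.00) were the most abundant. In the list of immediate-early and stress factors, 0 of 18 were called without the block, and 1 was higher and 4 lower with it (1 and 0 with the length trend removed as well), with crc at 0.04 and Xrp1 at −0.04.

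Among 24 heat shock and chaperone genes, Hsc70-2 was called, at 0.0447 ± 0.0148 CPM in controls and 0.395 ± 0.154 CPM after H2O2, and the other 23 were not; with the block, 2 were higher and 1 lower, and with the length trend removed as well 1 and 0. Inducible Hsp70 genes varied strongly among controls: Hsp70Ab had 2364, 1721 and 377 CPM in control replicates 1, 2 and 3, and 249, 587 and 450 CPM in the H2O2 replicates (log2 fold change −1.79, adjusted p = 0.241). Hsp70Bb (−1.84) and Hsp68 (−1.46) had values of the same sign, and were not called either (adjusted p = 0.334 and 0.326). Of 34 antioxidant genes, 1 was called, GstD10, a glutathione transferase gene (0.349 ± 0.0871 to 2.83 ± 0.932 CPM, log2 fold change 3.01), which lies 0.428 kb downstream of GstD9. With the block, 9 were higher and 2 lower, and with the length trend removed as well 2 and 0.

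In the unfolded protein list of 20 genes, Xbp1, a transcription factor gene of that response, was the 1 member called lower (950 ± 79.2 to 595 ± 69.4 CPM, log2 fold change −0.68, adjusted p = 0.045), and the block gave 1 higher and 7 lower. In the JAK/STAT list, TotA, a humoral stress gene, was called among 13 (0.0713 ± 0.0398 to 0.416 ± 0.0764 CPM), and the block gave 2 higher and 3 lower. In the metal list, the ferritin gene Fer2LCH was called among 7 (1.64 ± 0.107 to 4.32 ± 1.10 CPM), and the block gave 2 higher and 1 lower. In the Ras-ERK list, rho was called among 15, and the block gave 1 higher and 4 lower. No member was called by edgeR without the block in the lists for NF-kB (27 tested, Rel −0.65 and spz 0.00), p53 and DNA damage (22, Tctp 0.14 and Xrp1 −0.04), ecdysone (17, ImpL2 0.05 and crol −0.28) or cell cycle (30, stg 0.55 and Myc −0.47). With the block, 1 NF-kB gene was lower, 1 p53 gene higher and 4 lower, 1 ecdysone gene higher and 5 lower, and 1 cell cycle gene higher and 3 lower. Among them were stg (adjusted p = 0.004), Myc (0.00146) and crol (0.0127). With the length trend removed as well, stg was still called (0.0177), while Myc was not (−0.20, adjusted p = 0.139) and crol turned to 0.02 (0.876). In that fit, the higher and lower genes numbered 2 and 2 for unfolded protein, 2 and 0 for JAK/STAT, 1 and 0 for metal, 1 and 0 for Ras-ERK, 1 and 0 for NF-kB, 1 and 0 for p53, 4 and 0 for ecdysone, and 1 and 1 for cell cycle genes.

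In the Notch list, 5 of 12 members were higher and 0 lower over all genes tested. Adjusted over the list alone, 5 were higher and 2 lower, and with the block 6 were higher and 3 lower over all genes tested, or 7 and 0 with the length trend removed as well. E(spl)mbeta-HLH, a bHLH repressor gene, rose from 39.8 ± 1.16 to 91.7 ± 21.8 CPM (adjusted p = 0.0186). E(spl)m2-BFM had 1.97, E(spl)m3-HLH 1.51 and E(spl)mdelta-HLH 1.84. E(spl)m7-HLH had 0 counts in all 3 controls and 71 counts over the H2O2 libraries, at least 22.1-fold higher against a floor of 3 counts over the control group. The receptor gene N had −0.50 (adjusted p = 0.092) and was called lower with the block (0.00122), but had 0.01 with the block and the length trend removed. E(spl)mdelta-HLH lies 1.88 kb downstream of Nf1 on the same strand. The list passed camera (median log2 fold change 0.43, adjusted p = 0.0439), but not with the replicate block (adjusted p = 0.223) nor with an estimated correlation (adjusted p = 0.877), and passed fry, which tests against no change (adjusted p = 0.0339). With the length trend removed, camera gave an adjusted p of 7.46e-08 without the block and 1.59e-05 with it. With an estimated correlation these became 0.403 and 0.844. The trend may have been removed in excess in these tests, so no conclusion is drawn from them for the list. Its median was 0.82 without control replicate 1, 0.73 without H2O2 replicate 1 and 0.25 without H2O2 replicate 2, and it did not pass without H2O2 replicate 3 (adjusted p = 0.0616), without the low-count filter (0.0877) or with a filter of 50 counts in 3 libraries (0.0703).

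The other 3 lists that passed camera had small shifts, and none passed with an estimated correlation (adjusted p = 0.877 for each). All 80 ribosomal protein genes had positive fold changes (median 0.20, adjusted p = 3.16e-07), with 0 called, RpL5 at 0.11 and RpL35 at 0.18. All 69 nuclear oxidative phosphorylation genes were positive (median 0.20, adjusted p = 0.0159), and 1 was called, ATPsynbetaL (0.216 ± 0.0517 to 1.63 ± 0.424 CPM). ATPsynbetaL lies 1.68 kb downstream of the expressed gene ClC-c (log2 fold change −0.31) on the same strand. Of 19 glycolysis and pentose phosphate genes, 18 were positive (median 0.21, adjusted p = 0.0467), with CG8036 at 0.13 and PyK at 0.03 and 0 called. Adjusted over the list alone, 0 ribosomal, 1 oxidative phosphorylation and 0 glycolysis genes were higher without the block. With the block, that adjustment gave 65 of 80, 1 of 69 and 11 of 19 higher. It was not run with the length trend removed. With the block, 8, 9 and 7 genes of these lists were higher and 0 lower over all genes tested, and with the length trend removed as well 0, 1 and 2 were higher. Without H2O2 replicate 2 the ribosomal median was 0.11. The oxidative phosphorylation median was 0.38 without control replicate 1 and 0.34 without H2O2 replicate 3, and that list did not pass without control replicate 2 (adjusted p = 0.206), control replicate 3 (0.238) or H2O2 replicate 1 (0.984, median −0.04). Glycolysis passed in only 1 of the 6 fits that left out 1 library, without H2O2 replicate 3 (0.0451). These lists hold short transcripts. With the length trend removed, the medians of ribosomal protein and oxidative phosphorylation genes were 0.03 and 0.05, against −0.0046 over all genes. Camera gave both a negative sign (adjusted p = 0.00654 and 0.00468) and did not pass glycolysis (0.773). With the block as well, the adjusted p was 5.18e-06 and 0.000551, again negative, and 0.271, and with an estimated correlation it was 0.844 for each. The negative signs go against the medians, and these tests may remove the trend in excess, so no conclusion is drawn from them. The antioxidant list (median 0.17) missed the threshold (adjusted p = 0.0954) and passed with the block (0.0387), but not with the block and an estimated correlation (adjusted p = 0.805) nor with the block and the length trend removed, where the sign was negative (0.426) under that same limit. It passed without control replicate 1 (0.042, median 0.26) and without H2O2 replicate 3 (0.0464), with a filter of 50 counts in 3 libraries (0.0113) and in limma on log2(TPM + 1) (0.0031) and log2(TPM + 0.1) (0.00354). With an estimated correlation, the adjusted p in these fits was 0.795, 0.941, 0.891, 0.4 and 0.437. Its median was 0.09 without control replicate 3 and 0.06 without H2O2 replicate 1.

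**Figure D4:**
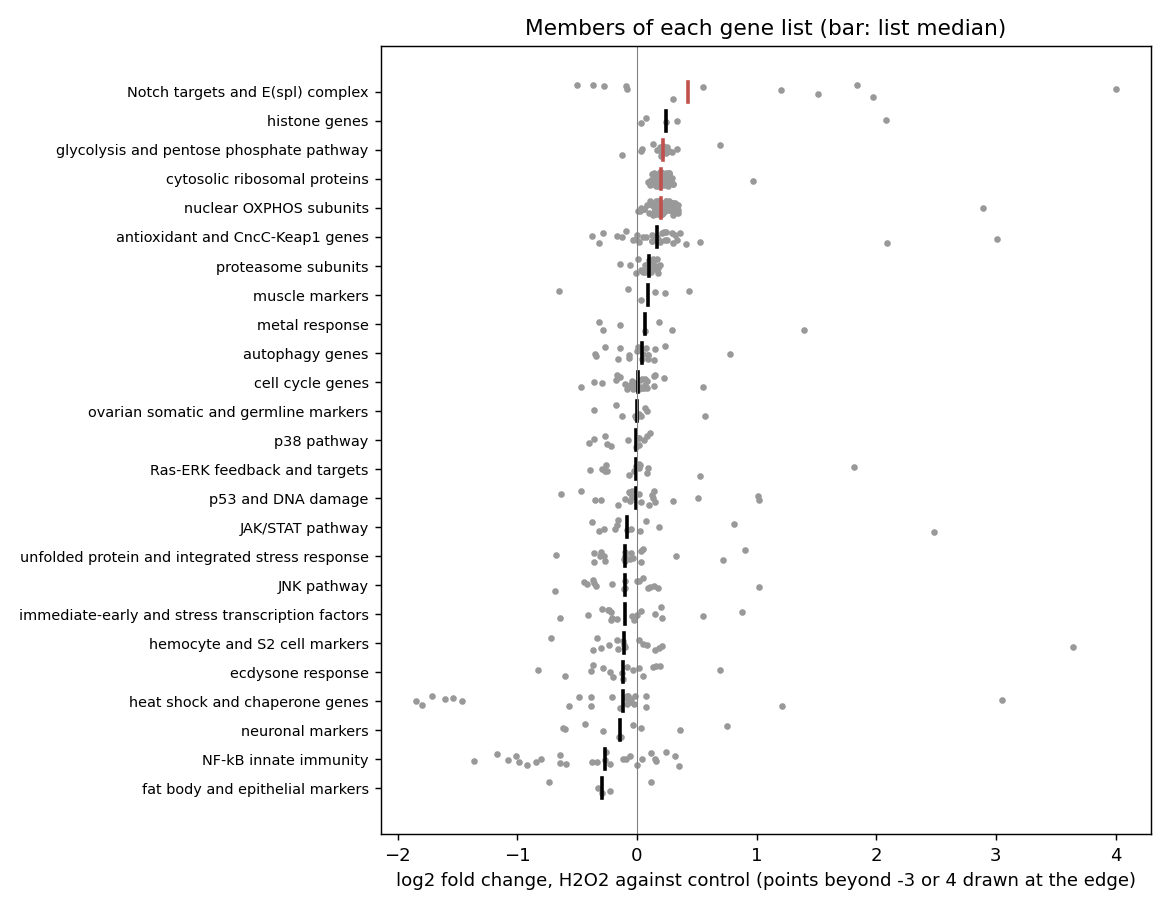
The log2 fold change of each tested member of 25 gene lists (points) with the list median (bar; red where camera passed). The Notch list has a median of 0.43 and the ribosomal protein list of 0.20.

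The remaining lists did not pass in the unblocked fit over all 6 libraries. Camera's adjusted p was 0.615 for proteasome genes (0 of 33 called, Prosalpha1R 0.10, Rpn2 −0.14), 0.148 for histones (1 of 5 called), 0.814 for autophagy genes (0 of 19, Atg8a 0.23, Atg2 −0.27), 0.563 for hemocyte markers (1 of 17), 0.716 for ovarian markers (0 of 10, zfh1 −0.12, bam 0.09), 0.273 for neuronal markers (0 of 10, brp −0.13, elav −0.43), 0.716 for muscle markers (0 of 6, Tm1 −0.08, Mlc2 0.23, with a median of 0.09) and 0.273 for fat body and epithelial markers (0 of 5, cora −0.30, Mtp −0.32). His2B:CG33868 was the called histone (0.423 ± 0.102 to 1.80 ± 0.784 CPM), and gcm, a glial and hemocyte transcription factor gene, the called hemocyte marker (0.0445 ± 0.0409 to 0.598 ± 0.189 CPM). With the block, 3 histone genes were higher, 1 autophagy gene higher and 3 lower, 1 hemocyte gene higher and 5 lower, 1 neuronal gene higher and 2 lower, 1 muscle gene lower, 2 fat body and epithelial genes lower, and 0 proteasome and ovarian genes were called. Among the lower were elav (adjusted p = 0.0021), Atg2 (0.027), cora (0.0466) and Mtp (0.0104). With the length trend removed as well, none of these 4 was called: elav had −0.13 (adjusted p = 0.466), Mtp −0.23 (0.097), Atg2 0.07 (0.539) and cora 0.02 (0.929), the last 2 with the sign turned. In that fit, 1 histone, 1 autophagy, 1 hemocyte, 2 neuronal, and 1 fat body or epithelial gene were higher, and 1 autophagy gene was lower. The autophagy (0.04), muscle (0.09) and cell cycle (0.01) lists had a positive median while the camera test was negative. For the stress lists, camera's adjusted p was 0.255 (p38), 0.273 (JNK), 0.615 (immediate-early), 0.387 (heat shock), 0.261 (unfolded protein), 0.716 (NF-kB), 0.562 (JAK/STAT), 0.64 (p53), 0.627 (metal), 0.135 (ecdysone), 0.64 (Ras-ERK) and 0.628 (cell cycle).

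Of these lists, 8 passed in at least 1 alternative with the preset correlation, and 0 with an estimated correlation in any of those fits (smallest adjusted p = 0.325). With the length trend removed, ecdysone (adjusted p = 0.000356, and 5.71e-05 with the block) and neuronal genes (0.00959 and 0.0429) passed with a positive sign and proteasome genes (0.0344 and 0.000237) with a negative one, each opposite to the sign without that removal, and JAK/STAT genes passed with a positive sign in the blocked fit (0.0429). The trend may have been removed in excess in these list tests, so the turned signs cannot be read as changes of the lists. Without control replicate 1, NF-kB (0.00969, median −0.56), ecdysone (0.0143, −0.22) and proteasome genes (0.00999, 0.30) passed. So did heat shock genes without control replicate 3 (0.000572, −0.34), ecdysone genes without H2O2 replicate 2 (0.0218, −0.19) and proteasome genes without H2O2 replicate 3 (0.0451, 0.23). Without both libraries numbered 3, heat shock genes passed without the block (0.000534) and with it (0.0121), and proteasome genes with it (0.0475); without both numbered 2, NF-kB genes passed with the block and a positive sign (0.0064, median 0.29). The p38 (0.0149) and ecdysone (0.0218) lists passed with a negative sign in limma on log2(TPM + 1) without a filter, the ecdysone list with an effective length offset (0.0445), and the histone list in limma on log2(TPM + 1) (0.0167) and log2(TPM + 0.1) (0.0171). The list test with the effective length offset may be overcorrected in the same way.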

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

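The test in this part was chosen after the result was seen. Genes below the count filter, which the edgeR fit with that filter did not test, held more signal after H2O2. These 7496 genes summed to 176, 198 and 206 CPM in control replicates 1, 2 and 3, and to 264, 358 and 294 CPM in H2O2 replicates 1, 2 and 3, a ratio of means of 1.58. Genes with a count above 0 among them numbered 2249, 2387 and 2285 in controls and 2663, 3129 and 2866 after H2O2.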

How the results depend on the processing

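Leaving out both libraries of a number and the estimated correlation in the alternative fits were chosen after seeing the data; the other alternatives were planned. The GC correction was not run, because no genome sequence was used here. The cause of the differences below was not tested.

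Against 281 changed, 230 higher and 51 lower genes, DESeq2 called 706, 360 and 346, a filter of 50 counts in 3 libraries 76, 60 and 16, limma on log2(TPM + 1) 32, 25 and 7, and limma on log2(TPM + 0.1) 44, 35 and 9. Library totals alone gave 29 lower genes, the removed length trend 10, and the test against a 1.2-fold change 16. The replicate block gave 1947, 805 and 1142, and the block with the length trend removed 681, 536 and 145. Leaving out 1 library gave 0 to 154 changed, 0 to 134 higher and 0 to 20 lower genes. Leaving out both libraries numbered 1, 2 or 3 gave 0, 0 and 0 changed genes in edgeR without the block, and so 0 higher and 0 lower, where 1578, 662 and 811 genes had an unadjusted p under 0.05. With the block, the counts were 1536, 768 and 1652 changed, 642, 361 and 732 higher, and 894, 407 and 920 lower.

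Of the gene lists, 4 passed with the preset correlation. The count was 1 without the low-count filter, 7 with the block and length trend removed, 1 with both libraries numbered 2 left out, 2 with both numbered 1 left out and the block, 1 by fry, which tests lists against no change, and 0 with an estimated correlation, in the unblocked fit over all 6 libraries and in each of 24 alternative fits (smallest adjusted p = 0.325). Leaving out 1 library gave 2 to 7 lists with the preset correlation and 0 with an estimated one. List counts with the length trend removed or an effective length offset may be overcorrected, as said above. The median of oxidative phosphorylation genes ranged from −0.038 (without H2O2 replicate 1) to 0.38.

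With the block, 17 of the named genes not called without it were called, and the block changed no other call among them except to turn the sign of kay and spz, both near 0. Unrounded counts changed no named gene's call. Among single genes, signs turned only for genes not called without the block, most of them near 0; with the block and the length trend removed, brp was called higher (adjusted p = 0.0154). The values by setting were as follows. Limma on log2(TPM + 1) gave crc −0.064, kay −0.083, ImpL2 −0.075, PyK −0.044, bam −0.014, p38a −0.067, p38b −0.033, Atf-2 −0.075, egr −0.069. Limma on log2(TPM + 0.1) gave crc −0.064, kay −0.083, ImpL2 −0.075, PyK −0.044, bam −0.015, p38a −0.067, p38b −0.034, Atf-2 −0.079, egr −0.069. Limma on log2(TPM + 1) without a filter gave crc −0.064, kay −0.083, ImpL2 −0.075, PyK −0.044, bam −0.014, p38a −0.067, p38b −0.033, Atf-2 −0.075, egr −0.069. Both libraries numbered 3 left out gave crc −0.023, kay −0.018, spz 0.012, ImpL2 −0.0018, p38a −0.082, lic 0.026, Atf-2 −0.041. Both libraries numbered 3 left out with the replicate block gave crc −0.031, kay −0.031, spz 0.014, ImpL2 −0.054, p38a −0.072, lic 0.021, Atf-2 −0.040. Library totals alone gave Xrp1 0.0094, spz 0.046, lic 0.033, Vha100-2 0.0085. Effective length offset gave Xrp1 0.060, spz 0.0036. Gene length trend removed gave Xrp1 0.038, chic −0.033, Lk6 0.021, crol 0.025, RpL5 −0.019, Prosalpha1R −0.033, Atg2 0.070, zfh1 0.24, brp 0.34, cora 0.0087, p38a −0.069, Atf-2 −0.085, N 0.013, Vha100-2 0.053. Replicate block and gene length trend removed gave Xrp1 0.036, chic −0.033, Lk6 0.017, crol 0.025, RpL5 −0.027, Prosalpha1R −0.032, Atg2 0.071, zfh1 0.24, brp 0.34, cora 0.018, p38a −0.062, Atf-2 −0.088, N 0.010, Vha100-2 0.052. Both libraries numbered 1 left out gave Xrp1 0.010, PyK −0.060, egr −0.0096. Both libraries numbered 1 left out with the replicate block gave Xrp1 0.033, PyK −0.060, egr −0.0092. DESeq2 Wald test gave kay −0.00096. DESeq2 size factors in edgeR gave kay −0.00095. No low-count filter gave kay −0.014. Replicate block gave kay −0.0029, spz 0.0028. Both libraries numbered 2 left out gave kay −0.020, lic 0.0032, egr −5.1e-06. Both libraries numbered 2 left out with the replicate block gave kay −0.024, ImpL2 −0.034. At least 50 counts in 3 libraries gave spz 0.019, lic 0.0062. When 1 library was left out, fold changes ranged as follows: crc −0.041 to 0.15, Xrp1 −0.26 to 0.21, kay −0.29 to 0.27, Rel −1.19 to 0.50, spz −0.090 to 0.058, ImpL2 −0.19 to 0.34, PyK −0.11 to 0.11, RpL5 −0.0080 to 0.25, Prosalpha1R −0.20 to 0.43, Rpn2 −0.36 to 0.015, bam −0.065 to 0.19, Mlc2 −0.060 to 0.68, p38a −0.15 to 0.25, p38b −0.034 to 0.12, lic −0.11 to 0.032, Atf-2 −0.062 to 0.075, egr −0.18 to 0.18. Genes under about 1 CPM rest on few counts, which limits their precision.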

Other observations

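Tests of the length trend, of neighbouring genes, of background over all genes, of histone and short transcripts, and of genes split by the overall mean were chosen after their results were seen; the genomic span, upstream gene and upstream level tests and the splits of the samples were not.

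Several stress genes were called only with the replicate block. Thor, a translation repressor gene, had a log2 fold change of 0.72 (blocked adjusted p = 0.000183, unblocked 0.505), the cytokine gene upd2 0.81 (0.00211 against 0.719), the cell death gene rpr 1.01 (0.00833 against 0.348), GstD1 0.41 (0.00329 against 0.33) and se 2.09 (0.00211 against 0.211). The value of se rests on few counts. It had 0.0806, 0.264 and 0.138 CPM in control replicates 1, 2 and 3. In H2O2 replicates 1, 2 and 3 it had 0.279, 1.31 and 0.482 CPM. In the other direction, Atf3 had −0.41 (0.00263 against 0.308), the chaperone gene Hsp83 −0.38 (0.0136 against 0.518) and the hemocyte gene Hml, with a transcript of 11755 nt, −0.72 (0.000195 against 0.0817). With the block and the length trend removed, GstD1 (adjusted p = 0.0679), Atf3 (0.865), Hsp83 (0.0593) and Hml (0.203) were no longer called, and the other 4 were. lncRNA:CR45204 had 606 counts over the controls and 0 in the H2O2 libraries, at least 212-fold lower against a floor of 3 counts over the H2O2 group. Its posterior SD was 32.8% of the count, so the division of its reads between genes was uncertain. The floor allows for counting alone, so a different division of reads could make the change smaller. asRNA:CR44370 had 0 counts in controls and 74 after H2O2, at least 23.6-fold higher, and lies 2.14 kb downstream of the expressed gene CG8079 on the same strand.

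One pattern is that near-silent genes were higher after H2O2. The neighbour comparison took only near-silent genes that passed the count filter, 1230 of 8717. Called genes lay within 5 kb downstream of an expressed same-strand gene in 67.3% of cases, against 42.3% of these uncalled genes. The odds ratio was 2.81 (95% interval 2.02 to 3.94), or 2.75 with genes split by the mean over all 6 libraries. For the other 3 orientations the odds ratios were 0.750, 0.993 and 0.672. The interval treats genes as independent, though some share an upstream gene, such as CG34184 and CG34442 downstream of Tfb1, so it may be too narrow. Background over all genes is argued against by the gain per kb beyond 50 kb, 0.0553 of that within 5 kb, and a rise of the upstream genes by their median log2 fold change of −0.021. Transcripts running on past the ends of expressed genes may be a candidate explanation, but the gain followed the upstream gene's level only weakly across genes (Spearman 0.191, permutation p = 1e-05, the smallest 100000 permutations can give, under the 0.2 set beforehand; Pearson 0.129 on log2 CPM, p = 3e-05; genes are not independent replicates), which leaves that part open. Read positions along these genes were not analysed here.

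Another pattern is that lower genes had long transcripts. Removing a smooth length trend took the median log2 fold change of the 51 genes from −0.72 (quartiles −0.78 and −0.63) to −0.21 (−0.33 and −0.12), which ended most calls because the fold changes shrank, so a trend over all genes may account for most of it, and 8 of them were still called lower. Loss of new transcripts from genes with a long genomic span predicted a negative correlation with span. The partial Spearman correlation with genomic span given transcript length was 0.0612, while that with transcript length given span was −0.53. Fold changes thus followed transcript length and not span. Total mRNA was measured and its turnover was not, so the test cannot decide on loss of new transcripts as such. RNA integrity or library preparation, and a biological loss of long mRNAs, cannot be told apart: the range of the length slope among controls was 0.758 of the mean difference between groups, yet the slope was lower after H2O2 in all 3 pairs, by −0.127, −0.195 and −0.134 per doubling.

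A further pattern is that 7SL, RNase MRP and RNase P RNAs were higher. Retention of short transcripts is argued against by the median log2 fold change of the other 85 genes of at most 400 nt, 0.20. Less complete poly(A) selection and altered processing of these RNAs after H2O2 cannot be told apart. Summed CPM of the histone cluster genes, whose mRNAs lack a poly(A) tail, had a ratio of 3.94, but 1 gene, His2B:CG33868, held 47 of the counts in controls and 215 after H2O2, and the other 110 genes held 5 in each group, too few to show whether the class moved.

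Among the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, only the real split (1 of 10) gave as many changed, higher or lower genes: 281, 230 and 51, against 0 for the highest of the others in each case. Of the others, 3 part all 3 pairs as the real split does, and with the block they gave 0 genes against 1947. In the other splits the difference between the real groups falls into the residual spread, which pushes their counts toward 0. No conclusion is therefore drawn from these gene counts. For the gene lists, 7 of the 10 splits passed as many as the real 4, with 13 the highest (control 1, H2O2 1 and H2O2 3 against the rest), which points to a structure of the samples that moves whole gene groups together. That split parts 1 pair, and the 3 others that part all 3 pairs passed 5, 2 and 3 lists.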
